A study of Mus musculus with 9 samples.

How the data were processed

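RNA of islets cultured for 3 days at 11.8, 20 or 35 mM glucose was made into libraries with CEL-Seq2, a method that tags the 3' end of transcripts with a sample barcode and a random molecular identifier (UMI), here from 3 ng of purified RNA, per the labels' protocols. Sequencing gave 15 bases of read 1 and 52 bases of read 2, and the UMI had 6 bases. The deposited values are read counts per gene and barcoded sub-library, 3 for each of the 9 samples, and the authors made them with cutadapt, TopHat and HTSeq on GRCm38.p4, per the submitters' processing notes, which also name DESeq2. Versions, the annotation and the counting strand are not given in the sources used here. The counts were not collapsed by UMI, since the highest count of a gene in a sub-library was 605402 and 16 genes exceeded the 4096 possible UMIs. Reads copied by amplification are not independent molecules, so any statement of depth covers counting error only.

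The 27 sub-libraries were tied to samples through the deposited sample sheet, whose sample names match the labels, and were summed to 9 libraries. Another deposited count table and a table of DESeq2 normalized values were not used here, because their column names are not the labels of these samples. In all 30 columns of per-sample values could not be tied to a sample, and no reported value rests on them. The design had tied the choice of count table to a match with the normalized values, a rule that could not be followed for that reason. Of 22145 features, 92 ERCC spike-in RNAs and 5 summary lines of the counting were left out of library sizes and tests. The summary lines held 19.6% to 29.9% of all counted reads per library, of which alignments that were not unique made up 12.6% to 22.6% and reads outside genes 5.79% to 8.58%. Spike-ins came to 0.0252% to 0.0322% of the gene counts. Of 22048 genes, 21781 were matched to a symbol by their Ensembl identifier in GENCODE M21 and 267 were not.

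Tests were run in R 4.3.3 with edgeR 4.0.16, using TMM normalization, filterByExpr by group. The model had a mean for each concentration over all 9 libraries (6 residual degrees of freedom), with the robust quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 9739 genes tested, and changes were called rises or falls only then. An exact permutation test of 3 libraries against 3 cannot give a p under 0.1, so that the calls rest on the model's sharing of spread across genes. Values in CPM used the TMM-scaled library sizes. The 29 gene lists were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 and again with an estimated correlation per list, adjusted over 87 tests. Design, gene lists, alternative settings and the rule for named genes were fixed before the data were examined.

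That rule named, for each comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM and no overlap between the libraries compared, leaving out predicted genes and pseudogenes. Where fewer than 5 passed in a direction, the genes with the smallest p up to 5 were named as values. From each list it named up to 4 called members, or the 2 with the smallest p where none was called, and it always named Ins1, Ins2, Gcg, Sst, Ppy, Mafa, Slc2a2, Ucn3 and Txnip. The text prints a part of these and gives the rest as counts. Of the called genes, 1 that the rule names is not reported here, though it stays in the counts and list tests. Outside it lie Serpini1, Fos and Pdyn at 35 against 11.8 mM, Arrdc4, Dapl1 and Pdyn at 35 against 20 mM, and Odc1, Srm, Pycr1, Sec11c, Bace2, Igf1r, Dusp6, Idh2 and Resp18, all chosen after their values were seen.

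Tested on 5 simulated data sets of the 35 against 11.8 mM comparison with all 9739 genes, the method called 12.5% of genes changed 1.5-fold, 51.9% of those changed 2-fold and 91.2% of those changed 4-fold, all with the right sign, and 26 of 47595 unchanged genes. A shifted list had a p under 0.05 by camera in 5 of 5 simulations and an unshifted list in 0 of 5. The simulated genes were drawn independently of each other, so this cannot show how the list test behaves where members move together. Acinar markers, for example, had an estimated correlation of 0.927 at 20 against 11.8 mM. The median standard error of a log2 fold change was 0.247 to 0.25, and the smallest called change was 0.508 at 35 mM and 0.595 at 20 mM. Alternatives were DESeq2 size factors, no filter, a filter of 10 CPM in 3 libraries, the DESeq2 1.42.0 Wald or likelihood ratio test with its own independent filtering in place of the expression filter, removal of the 20 most abundant genes, the replicate number as a block, each library left out, and fits of only the 2 concentrations compared. Single barcode sets, removal of 2 sub-libraries, an acinar covariate and the DESeq2 test on the 9739 genes of the expression filter were added after the data were seen.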

Results

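Gene expression was measured in pancreatic islets of ICR mice, an outbred laboratory strain, after 3 days of culture in medium with 11.8, 20 or 35 mM glucose. The series describes these concentrations as basal, hyperglycemic and extreme hyperglycemic. Each concentration had 3 libraries, and the islets came from 9 mice. The treatment text of the labels gives 25 mM for the highest concentration, whereas the titles, the sample characteristics and the series design give 35 mM, which was followed here. Libraries held 3228648 to 4559561 gene counts, and 13366 to 13923 genes had at least 1 count. The labels do not state that each library came from a separate mouse, so the p-values measure only the spread between these samples, which may be technical.

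The insulin genes Ins1 and Ins2 together took 53.5% ± 4.15 of the gene counts at 11.8 mM, 51.2% ± 2.61 at 20 mM and 51.5% ± 2.50 at 35 mM (mean ± SD, n = 3 libraries each). Mitochondrially encoded transcripts took 6.09% ± 0.407, 6.41% ± 0.740 and 5.45% ± 0.505. Digestive enzyme genes of acinar cells, the exocrine neighbours of islets, took 0.392% to 1.44% of the counts in the 11.8 mM libraries, 0.802% to 1.46% at 20 mM and 0.777% to 1.27% at 35 mM. Markers of fibroblasts and stellate cells took 0.0364% to 0.0717%, 0.0294% to 0.0463% and 0.0303% to 0.0523% at the 3 concentrations. Macrophage and other immune markers took 0.0158% to 0.0194%, 0.0142% to 0.0184% and 0.0117% to 0.023%.

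**Figure D1:**
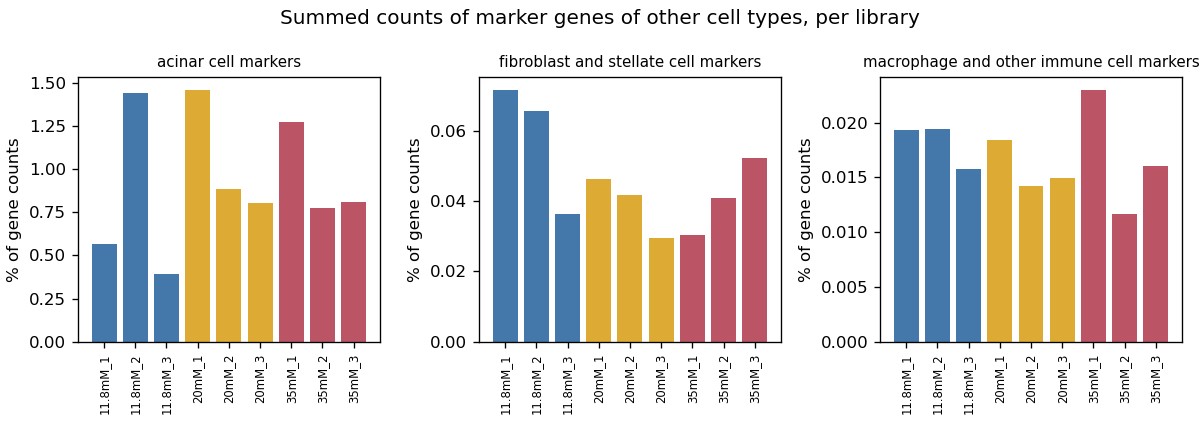
Share of gene counts (%, linear axes from 0) taken by the summed markers of acinar cells, fibroblasts and stellate cells, and macrophages and other immune cells, 1 bar per library. Acinar markers ranged from 0.392% to 1.46% over the 9 libraries, with 1 library at each concentration at 1.27% or more.

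The effect of extreme glucose on the islet program was addressed by comparing 35 with 11.8 mM. Among called genes with a mean of at least 10 CPM, the read count scaled by library size, large rises were those of Dlk1, an imprinted gene for a membrane protein of the Notch ligand family, and Txnip, a thioredoxin-binding protein whose gene responds to glucose. Dlk1 rose from 9.17 ± 1.76 to 48.4 ± 5.16 CPM (mean ± SD, n = 3), a log2 fold change of 2.41 ± 0.21 (SE; adjusted p = 8.65e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Txnip rose from 13.1 ± 0.5 to 48.8 ± 3.88 CPM (log2 fold change 1.90 ± 0.18; adjusted p = 2.55e-08). Of 9739 genes tested, 61 rose and 23 fell, and 32 of these 84 changed by more than 2-fold.

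Dapl1, a gene of little known function in islets, rose from 48.9 ± 11.9 to 152 ± 12.7 CPM (log2 fold change 1.63), and Vgf, a granule protein and peptide precursor, rose by 1.22. Iapp, the amyloid peptide co-secreted with insulin, rose from 13710 ± 434 to 21159 ± 564 CPM (log2 fold change 0.63 ± 0.13; adjusted p = 0.00865). Ttr, which encodes transthyretin, rose by 0.67, and Pcsk1, a proinsulin-processing convertase, by 0.68. Large log2 fold changes were also measured in Slco1a5, an organic anion transporter (1.62), and Tacr3, the neurokinin B receptor (1.49). Aqp4, a water channel, rose (1.46), as did Slc7a3, a cationic amino acid transporter (1.43). So did Tnfrsf23, a decoy death receptor (1.35), and Rspo4, a Wnt pathway agonist (1.24). Above the same level the largest falls were those of Cib3, a calcium-binding protein (-1.83), Defb1, a defensin (-1.18) and Junb, an immediate early transcription factor (-1.12). Falls were also called for Cryl1 (-1.02), Ccdc12 (-0.99), Coprs (-0.94), Trpm5, a calcium-activated cation channel (-0.93), Sult1d1, a sulfotransferase (-0.91), and Calcoco1 (-0.91). Vegfb, a growth factor, fell from 25.6 ± 1.82 to 12.8 ± 2.47 CPM. Slco1a5 and Tnfrsf23 belong to multigene families, and exons of Junb, Trpm5, Tnfrsf23, Ptprn and Txnip overlap genes on the opposite strand, so that their counts are uncertain where the counting could not separate the copies or the strands.

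Targets of ChREBP, the transcription factor that responds to glucose metabolites, rose as a list at 35 mM (9 genes tested, median log2 fold change 1.34, adjusted p = 1.15e-16 by camera; adjusted p = 0.00466 with an estimated correlation). Of the 9, 3 rose over all genes tested, among them Txnip and Arrdc4 (1.39 ± 0.30), and 6 did not pass, whereas 7 rose when adjusted over the list alone. The list of secretory granule and exocytosis genes rose (21 genes, median 0.15, adjusted p = 9.27e-05; adjusted p = 0.471 with an estimated correlation). Its members Vgf, Chgb (0.78), Ptprn (0.78) and Scg3 (0.59) rose, 17 did not pass, and 5 rose when adjusted over the list alone. Markers of dedifferentiated beta cells rose as a list (11 genes, median 0.43, adjusted p = 1.19e-04; adjusted p = 0.471 with an estimated correlation). In it 9 members did not pass and 4 rose when adjusted over the list alone. The 2 that rose over all genes were the peptide hormone genes Cck (1.92 ± 0.34; adjusted p = 0.00207) and Gast (1.45 ± 0.34; adjusted p = 0.0241), both of gut-type hormones. Their levels were low. Cck and Gast stood at 13.2 ± 3.88 and 10.9 ± 1.66 CPM at 35 mM, against 3.41 ± 0.959 and 3.88 ± 1.68 at 11.8 mM.

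The list of genes that define beta cell identity was not called (20 genes, median log2 fold change -0.09, adjusted p = 0.684). Within it Iapp and Pcsk1 rose, Trpm5 fell and 17 did not pass, against 4 that rose and 5 that fell when adjusted over the list alone. Neither insulin gene passed, with log2 fold changes of 0.10 ± 0.14 for Ins1 and -0.24 ± 0.17 for Ins2, the latter at 330810 ± 87465 and 280720 ± 57312 CPM. In 1 of the 3 sub-libraries of 11.8 mM replicate 1 Ins1 took 11.8% of the gene counts against 26.3% in the other sub-libraries of that sample, and in 1 of those of 35 mM replicate 1 Ins2 took 10.6% against 29%, so that the insulin values differed between sub-libraries of 1 sample. Without both of these sub-libraries the log2 fold changes were -0.01 for Ins1 and -0.11 for Ins2. Ucn3, a peptide of mature beta cells, had a log2 fold change of -0.42 ± 0.13 (adjusted p = 0.178), and Slc2a2, the glucose transporter of beta cells, -0.28 ± 0.15 (adjusted p = 0.542). Hormone genes of other islet cells had values of -0.24 ± 0.13 for Gcg, 0.14 ± 0.15 for Sst and -0.01 ± 0.17 for Ppy, none of which passed. Mafa, a transcription factor of beta cells, did not pass the expression filter and was not tested.

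Immediate early genes, which respond within minutes to stimulation or handling, fell as a list (10 genes, median log2 fold change -0.52, adjusted p = 5.86e-07; adjusted p = 0.113 with an estimated correlation). Junb fell from 54.3 ± 15 to 24.9 ± 4.1 CPM, 8 did not pass, and 4 fell when adjusted over the list alone. Btg2 fell by 0.77 on the log2 scale, a call kept in 7 of 22 alternatives (range -1.04 to -0.27) and lost with the acinar covariate, under the replicate block and without any 1 of 7 libraries, namely 11.8 mM replicate 3 and each library at 20 and 35 mM. Fos had a value of -0.89 ± 0.27 (adjusted p = 0.134). Beside this, fibroblast and stellate markers fell as a list (12 genes, median -0.42, adjusted p = 0.00376; adjusted p = 0.519 with an estimated correlation). Macrophage and other immune markers fell too (12 genes, median -0.24, adjusted p = 0.0328; adjusted p = 0.471 with an estimated correlation). No member of either passed over all genes, Col1a2 standing at -0.60 and Fcer1g at -0.94, and 0 and 2 fell when adjusted over the list alone. Cell cycle genes fell as a list (20 genes, median -0.48, adjusted p = 2.54e-04; adjusted p = 0.471 with an estimated correlation). None of them passed over all genes and 3 fell when adjusted over the list alone. Top2a, the mitotic topoisomerase, stood at -0.64 ± 0.19.

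Genes of the unfolded protein response, which expand the folding capacity of the endoplasmic reticulum, rose as a list (21 genes, median 0.21, adjusted p = 0.00119; adjusted p = 0.519 with an estimated correlation). No member passed either adjustment, and the chaperone gene Hsp90b1, whose exons overlap genes on both strands, stood at 0.37 ± 0.12. Genes of the integrated stress response rose as a list (18 genes, median 0.11, adjusted p = 0.017; adjusted p = 0.519 with an estimated correlation). Over all genes 0 passed, and 3 rose when adjusted over the list alone. In it the serine synthesis gene Phgdh had 0.89 ± 0.25 (adjusted p = 0.0879). Nuclear genes of oxidative phosphorylation rose as a list (26 genes, median 0.12, adjusted p = 0.00685; adjusted p = 0.519 with an estimated correlation). Over all genes 0 passed, 1 rose when adjusted over the list alone, and Cycs, cytochrome c, stood at 0.51 ± 0.13. Mitochondrially encoded transcripts fell as a list (13 genes, median -0.16, adjusted p = 0.0453; adjusted p = 0.8 with an estimated correlation). The hexosamine pathway rose (6 genes, median 0.29, adjusted p = 0.0291; adjusted p = 0.471 with an estimated correlation). No member of either list passed either adjustment. The mitochondrial call was lost without 11.8 mM replicate 2 or 3, 20 mM replicate 2 or 35 mM replicate 1 or 2 (highest adjusted p = 0.76 by camera). Of 9 fits that each left out 1 library, 6 kept the call of the integrated stress response (highest adjusted p = 0.0934), 7 each those of oxidative phosphorylation (0.271), the hexosamine pathway (0.138), fibroblast (0.173) and macrophage markers (0.395), and 8 that of the cell cycle (0.0883). The osmotic response list was not called (5 genes, mean -0.06, adjusted p = 0.806), and no osmotic control is named in the labels.

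At 35 mM 1024 genes had an unadjusted p under 0.05, and in 1453 (14.9%) the libraries of the 2 concentrations did not overlap. Chance gives 10% on average over splits, but the spread of that share between splits was not computed, so an excess cannot be judged. The count of 84 became 138 without 11.8 mM replicate 1, 47 without 11.8 mM replicate 3, 41 without 35 mM replicate 1, 54 without 35 mM replicate 2 and 148 without the expression filter. Dlk1, Txnip, Dapl1, Vgf and Chgb kept their calls in all 22 alternatives run, whereas Gstm1 kept its call in 13, Ccdc12 and Coprs in 15, Defb1, Sult1d1 and Scg3 in 16, and Gast in 13 and Arrdc4 in 15 of the 19 that tested them.

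**Figure D2:**
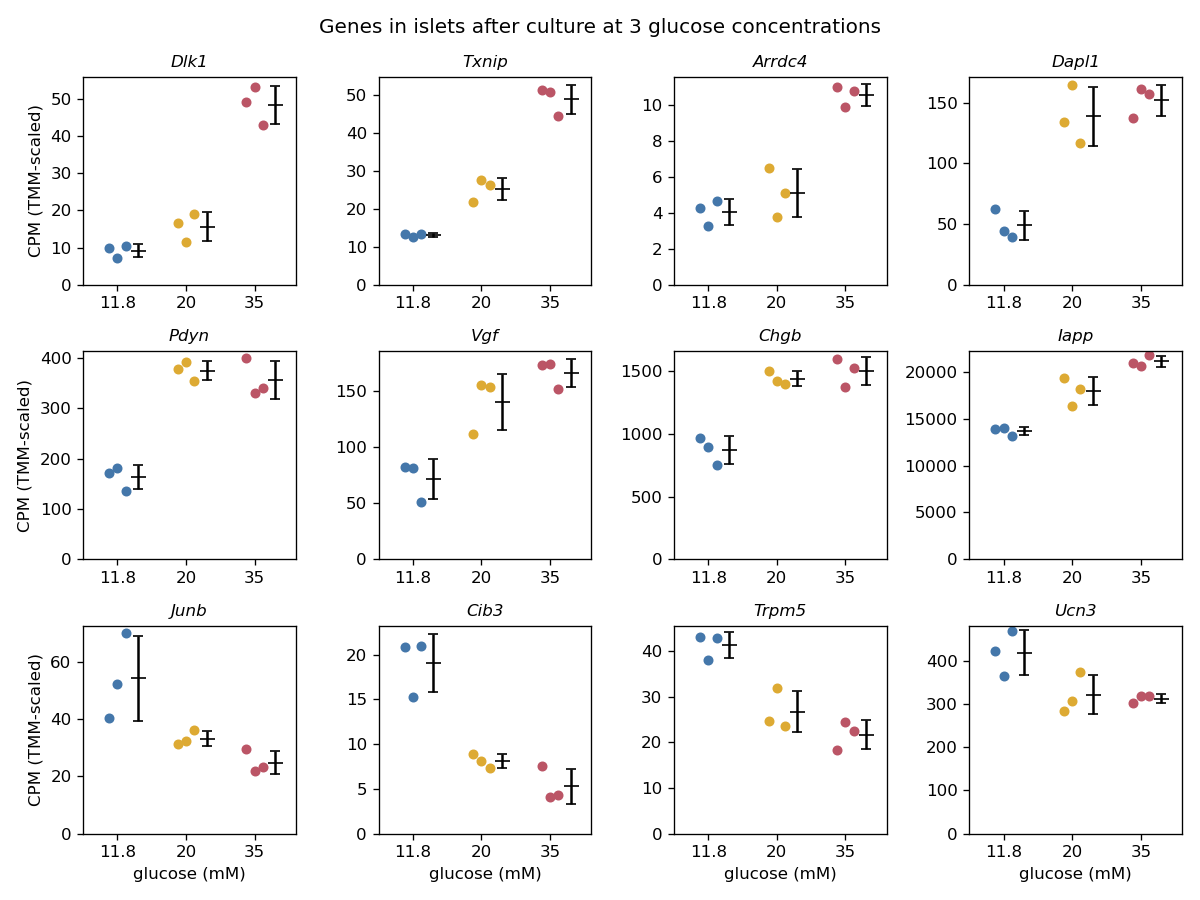
Level of 12 genes in CPM (linear axes from 0) against glucose concentration in mM, with 1 point per library and, beside the points, the mean ± SD of 3 libraries. Dlk1 stood at 9.17 ± 1.76, 15.6 ± 3.86 and 48.4 ± 5.16 CPM at 11.8, 20 and 35 mM, whereas Pdyn stood at 164 ± 24, 375 ± 19.4 and 357 ± 37.8.

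The response to the lower of the raised concentrations was addressed by comparing 20 with 11.8 mM. The clearest rises were those of Dapl1, from 48.9 ± 11.9 to 139 ± 24.2 CPM (n = 3; 2.84-fold; adjusted p = 2.13e-06 by edgeR), and of Pdyn. The latter, which encodes prodynorphin, an opioid peptide precursor, rose from 164 ± 24 to 375 ± 19.4 CPM (log2 fold change 1.20 ± 0.14; adjusted p = 3.09e-06 by edgeR). Vgf rose by 0.97 ± 0.16 (adjusted p = 0.00526) and Nucb2, the nesfatin precursor, by 0.91 ± 0.15 (adjusted p = 0.00237). Txnip rose by 0.95 ± 0.18 (adjusted p = 0.0116), to 25.2 ± 2.97 CPM. In all 15 genes rose and 3 fell, the latter being Cib3 (-1.22 ± 0.25), Dapk1, a death-associated kinase (-1.14 ± 0.22), and Gstm1, a glutathione transferase of a multigene family (-0.61 ± 0.13). Of falls, 0 were called without 20 mM replicate 1, and 1 without 20 mM replicate 3 or with the acinar covariate. The call of Cib3 was lost without 11.8 mM replicate 1 or 3 or any library at 20 mM, and that of Dapk1 without 11.8 mM replicate 3 or 20 mM replicate 1 or 3. Slco1a5 (1.30), Tnfrsf23 (1.27) and Tent5a, a poly(A) polymerase (0.85), also rose.

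The list of genes of the unfolded protein response rose (21 genes, median log2 fold change 0.29, adjusted p = 1.92e-07; adjusted p = 0.471 with an estimated correlation). Pdia6, a disulfide isomerase whose exons overlap a gene on the opposite strand and whose count is uncertain for that reason, rose by 0.60 ± 0.13 (adjusted p = 0.0489), 20 did not pass, and 9 rose when adjusted over the list alone. The secretory granule list rose (21 genes, median 0.11, adjusted p = 0.00331; adjusted p = 0.519 with an estimated correlation). In it Vgf and Chgb (0.73 ± 0.13) rose, 19 did not pass and 5 rose when adjusted over the list alone. Dedifferentiation markers rose as a list (11 genes, median 0.49, adjusted p = 0.0053; adjusted p = 0.519 with an estimated correlation). No member passed and 3 rose when adjusted over the list alone. Gc, the vitamin D binding protein, stood at 0.67 ± 0.16 and Cck at 1.28 ± 0.36. Oxidative phosphorylation genes rose as a list (26 genes, median 0.19, adjusted p = 6.75e-05; adjusted p = 0.471 with an estimated correlation). None passed, 3 rose when adjusted over the list alone, and Ndufa1, a complex I subunit, stood at 0.58 ± 0.13. The hexosamine pathway rose (6 genes, median 0.17, adjusted p = 0.046; adjusted p = 0.471 with an estimated correlation). Again none passed, and 1 rose when adjusted over the list alone. The hexosamine call was lost without 11.8 mM replicate 1 or 2, 20 mM replicate 2 or 3 or 35 mM replicate 2 (highest adjusted p = 0.174 by camera), whereas 8 of the 9 fits without 1 library kept that of the secretory granule list (highest 0.0931) and 7 that of the dedifferentiation markers (0.205). ChREBP targets were not called at 20 mM (median 0.33, adjusted p = 0.0868).

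Immediate early genes fell as a list at 20 mM (10 genes, all 10 with a negative value, median -0.38, adjusted p = 9.27e-05; adjusted p = 0.225 with an estimated correlation). None passed, 2 fell when adjusted over the list alone, and Junb stood at -0.70 ± 0.18. Acinar markers rose as a list (18 genes, median 0.38, adjusted p = 0.00434; adjusted p = 0.795 with an estimated correlation). No member passed either adjustment, and the zymogen granule gene Zg16 stood at 0.80 ± 0.61. Fibroblast and stellate markers fell (12 genes, median -0.41, adjusted p = 0.00308; adjusted p = 0.519 with an estimated correlation). Macrophage and other immune markers also fell (12 genes, median -0.27, adjusted p = 0.046; adjusted p = 0.471 with an estimated correlation), and no member of either list passed either adjustment. The macrophage call was lost without 11.8 mM replicate 2, 20 mM replicate 2 or 3 or 35 mM replicate 2 (highest adjusted p = 0.275 by camera), and the acinar call without 11.8 mM replicate 1 or 3 or 20 mM replicate 1 (0.314). That of the fibroblast markers was lost without 11.8 mM replicate 2 or 20 mM replicate 3 (0.272). Of the beta cell identity list only Pcsk1 (0.75 ± 0.13) rose and 19 did not pass, against 3 that rose and 3 that fell when adjusted over the list alone. Ins1 stood at -0.08 ± 0.14, Ins2 at -0.07 ± 0.17, Gcg at -0.12 ± 0.13, Sst at 0.11 ± 0.15, Ppy at 0.21 ± 0.17, Ucn3 at -0.38 ± 0.13 and Slc2a2 at -0.30 ± 0.15, none of which passed. Among alpha cell markers Ttr rose by 0.60 ± 0.13 (adjusted p = 0.0489).

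At 20 mM 776 genes had an unadjusted p under 0.05 and in 1249 (12.8%) the libraries did not overlap. Chance gives 10% on average over splits, with a spread that was not computed. The count of 18 became 35 without 11.8 mM replicate 2, 7 without 20 mM replicate 1, 9 without 20 mM replicate 3, 11 with the acinar score as a covariate, 51 without the expression filter and 34 with DESeq2 on the genes of that filter, and an equal 18 came from a split of the 6 libraries that set 11.8 mM replicates 1 and 3 and 20 mM replicate 3 against the rest. Dapl1 and Pdyn kept their calls in all 22 alternatives, Txnip in 16, Gstm1 and Tent5a in 8 and Pdia6 and Ttr in 6, and of the 21 that gave them an adjusted p Tnfrsf23 kept its call in 15, Dapk1 in 14 and Cib3 in 12.

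Whether the extreme concentration differed from the lower of the raised ones was addressed by comparing 35 with 20 mM. Of the genes tested 3 passed and rose, and 0 fell, though 4 rose and 3 fell without 35 mM replicate 3. Among the 3 Dlk1 rose from 15.6 ± 3.86 to 48.4 ± 5.16 CPM (n = 3; log2 fold change 1.64 ± 0.19; adjusted p = 1.77e-05 by edgeR) and Txnip from 25.2 ± 2.97 to 48.8 ± 3.88 CPM (log2 fold change 0.95 ± 0.16; adjusted p = 0.0075 by edgeR). ChREBP targets rose as a list (9 genes, median 0.95, adjusted p = 2.95e-16; adjusted p = 0.00466 with an estimated correlation), all 9 with a positive value. Of its members 2 rose, among them Txnip, 7 did not pass, Arrdc4 stood at 1.06 ± 0.29, and 5 rose when adjusted over the list alone. Dapl1, at 0.13 ± 0.15, and Pdyn, at -0.07 ± 0.13, did not pass.

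Against 11.8 mM the list of glycolysis genes was not called at 20 mM (median -0.18, adjusted p = 0.0665 by camera). Nor was it called at 35 mM (median -0.0027, adjusted p = 0.54 by camera). From 20 to 35 mM this list rose (15 genes, median 0.21, adjusted p = 0.00169 by camera, or 0.597 with an estimated correlation). The pyruvate kinase gene Pkm stood at 0.38 ± 0.15. Fatty acid synthesis genes rose (12 genes, median 0.20, adjusted p = 0.0053; adjusted p = 0.471 with an estimated correlation), and the desaturase gene Scd2 stood at 0.35 ± 0.15. Integrated stress response genes rose (18 genes, median 0.12, adjusted p = 0.0302; adjusted p = 0.519 with an estimated correlation), with Shmt2, a mitochondrial enzyme of serine breakdown, at 0.46 ± 0.14. Cell cycle genes fell as a list (20 genes, median -0.38, adjusted p = 3.01e-04; adjusted p = 0.471 with an estimated correlation), with Top2a at -0.44 ± 0.19. In these lists 0 members passed over all genes or when adjusted over the list alone. The integrated stress response call was lost without 20 mM replicate 1 or 3 or 35 mM replicate 1 or 2 (highest adjusted p = 0.175 by camera), and the glycolysis call without 35 mM replicate 2 (0.172). Mitochondrially encoded transcripts fell as a list (13 genes, all 13 with a negative value, median -0.22, adjusted p = 9.27e-05; adjusted p = 0.519 with an estimated correlation). Over all genes 0 passed, 1 fell when adjusted over the list alone, and mt-Nd2 stood at -0.49 ± 0.15. Outside the lists Aqp4 stood at 0.81 ± 0.19 and Zc3h7b at 0.75 ± 0.18, neither of which passed. On the negative side Ccdc34 stood at -0.82 ± 0.21, Adam32 at -0.82 ± 0.21, Rnf141 at -0.71 ± 0.21 and Cryl1 at -0.70 ± 0.22, none of which passed. Exons of Shmt2, Rnf141 and Zc3h7b overlap genes on the opposite strand and those of Pkm, Scd2, Top2a and mt-Nd2 genes on the same strand, so that their counts are uncertain. Of the genes tested 515 had an unadjusted p under 0.05 and 1160 (11.9%) did not overlap, where chance gives 10% on average with a spread not computed. The count of 3 became 1 without 20 mM replicate 3 and 7 without 35 mM replicate 3, and Dlk1 kept its call in 21 of 22 alternatives and Txnip in 15.

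**Figure D3:**
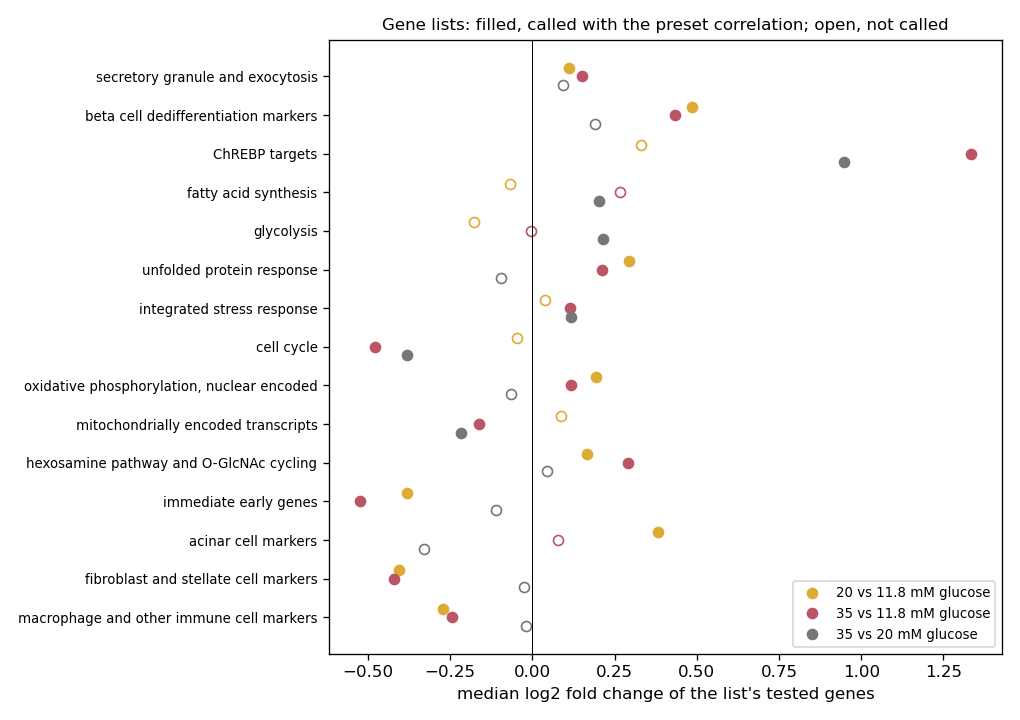
Median log2 fold change (x axis) of the tested genes of each gene list called in at least 1 comparison, with a point for 20 against 11.8, 35 against 11.8 and 35 against 20 mM. Filled points mark lists called by camera with the preset correlation, of which only the ChREBP targets at 35 mM, with medians of 1.34 and 0.95, were also called with an estimated correlation.

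Over the 3 concentrations together 59 genes differed by edgeR's quasi-likelihood F test, and 881 had an unadjusted p under 0.05. The count became 34 without 11.8 mM replicate 3, 37 without 35 mM replicate 1, 36 without 35 mM replicate 2 and 126 without the expression filter. Of 87 list tests 27 were called with the preset correlation and 2 with an estimated one, and 9 of 100 splits of the 9 libraries gave at least 27 list calls. Of the 29 lists 14 were called in no comparison. Their lowest adjusted p values by camera were 0.684 for beta cell identity, 0.243 for alpha cell markers, 0.508 for delta and PP cell markers, 0.252 for genes normally kept low in beta cells, 0.127 for cholesterol synthesis, 0.531 for the hypoxia response, 0.171 for the NRF2 response, and 0.333 for p53 targets. They were 0.714 for inflammatory chemokines, 0.0847 for the interferon response, 0.363 for the osmotic response, 0.531 for duct markers, 0.0708 for endothelial markers and 0.771 for Schwann cell markers. Median, mean and test differed in sign in 8 list tests, of which 0 were called.

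How far the 2 raised concentrations moved the same genes was addressed by the overlap of both comparisons with 11.8 mM. Of the 18 genes called at 20 mM, 13 rose and 2 fell at both concentrations, among them Dapl1, Pdyn, Vgf, Chgb, Pcsk1, Txnip, Cib3 and Gstm1, and 0 went opposite ways. The number of shared genes changed widely when single libraries were left out, as given in the section on processing. Dapk1, Pdia6 and Serpini1, a serine protease inhibitor gene, were called at 20 mM and did not pass at 35 mM. In 30 simulations of unchanged groups sharing the controls the mean overlap was 0.2 genes that rose and 0.133 that fell. Those simulated comparisons called a mean of 1.07 genes each, against 18 and 84 here, which keeps their overlap near 0 whatever the controls add. Independent lists of the observed sizes would share 0.094 and 0.00708. Across genes, which are not independent replicates, the fold changes had a correlation of 0.571 against a simulated 0.491. Their covariance was 0.0668 against a simulated 0.0439 (range 0.0411 to 0.0463). The simulated genes were drawn independently of each other, so that range may be too narrow where real genes move together. Whether the covariance exceeds chance therefore cannot be judged. The 3 control libraries were not split between the comparisons, since 1 part would have held a single library, so part of the overlap may come from the shared controls.

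The genes named above lie on the mouse assembly GRCm38, with positions from the GENCODE M21 annotation, in which each of the following is a protein-coding gene. Dlk1 (ENSMUSG00000040856) lies on chromosome 12 from 109452823 to 109463336, Txnip on chromosome 3 from 96557957 to 96561883, and Dapl1 on chromosome 2 from 59484653 to 59505020. Pdyn lies on chromosome 2 from 129686565 to 129699844, Vgf on chromosome 5 from 137026392 to 137033351, Iapp on chromosome 6 from 142298423 to 142303961, Junb on chromosome 8 from 84974484 to 84978718 and Cib3 on chromosome 8 from 72204335 to 72212837. Ins1 lies on chromosome 19 from 52264297 to 52265476 and Ins2 on chromosome 7 from 142678656 to 142743381. The counts are of whole genes, so that no exon, intron or untranslated region is told apart.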

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

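The tests of the acinar covariate, of the fit without 2 sub-libraries, of the osmotic list and of the insulin reads were chosen only after the results they measure had been seen. Alignments that were not unique, which no comparison used, made up 22.6% of the reads of 35 mM replicate 1, above the highest value in the 11.8 mM libraries, 21.9% in replicate 1.

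Both high values came from a single sub-library each, the third of its sample, with shares of 35.16% and 39.48% against 11.26% to 17.04% in the others. The gene profile of both differed from that of their sibling sub-libraries, with a chi-square per degree of freedom of at least 20.71 against 2.03 to 4.11 for the others, a value that came down to 1.92 and 2.23 without Ins1 and Ins2. A candidate explanation is that insulin reads were counted as not unique in these sub-libraries. The missing insulin counts came to only 0.416 and 0.464 of the excess non-unique alignments, below the bound of 0.5 set for the test, which argues against this as the whole account if each read was tallied once. A tally of every alignment of a read would lower the ratio, and how HTSeq was set is not given in the sources used here. No biological explanation was tested.

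At 35 mM 84 genes were called, and glucose is the biological difference the design names. With the acinar score as a covariate 74 of the 84 were still called, and without the 2 sub-libraries 66 were. All 84 kept their sign in both, but those tested kept it in every other setting too, so the sign adds no support. The counts still called argue against acinar carry-over or these sub-libraries as the whole cause. The bounds for this reading were set after both values had been seen and were not alike, 4 of 5 for the covariate and 3 of 4 for the sub-libraries. At 4 of 5, or 68 genes, the second value would have fallen short, so that reading is the weaker of the pair. An osmotic load stays open, since the osmotic response list had a mean log2 fold change of -0.0626 ± 0.0748 (SE over 5 members) and no osmotic control is named, so that it and glucose cannot be told apart.

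Of the 10 splits of 6 libraries, 1 gave as many genes as the 84 at 35 against 11.8 mM (highest other 6), 2 as many as the 18 at 20 against 11.8 mM (highest other 18) and 1 as many as the 3 at 35 against 20 mM (highest other 0), and 10 splits are too few for a share under 0.05. The other split with 18 genes set the libraries with the 3 lowest acinar shares, 0.392% to 0.802%, against those with 0.883% to 1.46%. With the acinar score as a covariate 11 of the 18 real calls stayed and all 18 kept their sign. The 7 lost genes had 0.864 to 0.967 times their log2 fold change and 1.04 to 1.16 times its SE, as Gstm1 at -0.61 ± 0.13 before and -0.58 ± 0.14 after, or Pdia6 at 0.60 ± 0.13 and 0.57 ± 0.15. Their calls ended through slightly smaller folds and larger errors together (adjusted p 0.0758 to 0.195 by edgeR with the covariate). No bound was set for this comparison, so these values do not decide for or against a part of acinar carry-over. Over 100 drawn splits of 280 of the 9 libraries, the real split included, only the real one gave as many as 59 genes. The highest other count was 54, in a split that kept the 11.8 mM libraries together. A share of 1 in 100 argues against chance for that count only if the libraries are independent samples, which the labels do not state. The rest of the 280 splits were not run. For the 27 list calls 9 of 100 drawn splits gave as many (highest other 37), so chance is not excluded for their number.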

How the results depend on the processing

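The single barcode sets, the fit without 2 sub-libraries, the acinar covariate and DESeq2 on the filtered genes were chosen after seeing the data, and the other deposited count table, a setting listed beforehand, was not run because its columns could not be tied to samples. The cause was not tested for any of the shifts below, except that single barcode sets and left-out libraries hold fewer reads or samples by construction. The called named genes kept their sign in each setting run, and 43 of 3630 values of uncalled named genes changed sign. Over named genes and settings listed beforehand 117 values lost and 35 gained a call, 60 moved and 3256 stayed, and over lists 65 lost and 21 gained it. In added settings 99 gene values lost and 8 gained a call and 138 moved, and 33 list values lost and 6 gained it. DESeq2 gave no adjusted p for 8 values of called and 41 of uncalled named genes, which were left out. Each barcode set alone held fewer reads and called 12 to 42 genes at 35 against 11.8 mM, against 84, and the parts of depth and of spread between sub-libraries in this were not told apart.

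Without a filter the counts were 51 genes at 20 against 11.8 mM, 148 at 35 against 11.8 mM and 126 over the 3 concentrations, with 33 shared by both comparisons with 11.8 mM. DESeq2, whose own filtering over 15985 genes replaced the filter so that test and filter changed together, called 51 at 20 against 11.8 mM, with 37 shared. On the 9739 filtered genes it called 34, among them all 18, with 24 shared. Fitting only the 2 concentrations compared gave 11 at 20 against 11.8 mM and 9 shared. An estimated correlation left 2 list calls of 27. Barcode set 1 alone gave 2, 12, 1 and 8 genes at 20 against 11.8, 35 against 11.8, 35 against 20 mM and over all, 2 shared genes and 15 list calls. Set 2 alone gave 8, 42, 1 and 29 genes, 7 shared and 17 list calls. Set 3 alone gave 39 at 35 against 11.8 mM, 1 at 35 against 20 mM, 32 over all and 8 shared. The acinar covariate gave 11 at 20 against 11.8 mM and 6 at 35 against 20 mM.

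Leaving out 1 library gave 7 to 35 genes at 20 against 11.8 mM, 41 to 138 at 35 against 11.8 mM, 1 to 7 at 35 against 20 mM, 34 to 75 over all, 7 to 28 shared genes and 20 to 29 list calls. The Schwann cell list at 35 against 11.8 mM was not called in the main fit. Its mean ran from -0.77 without 35 mM replicate 3, a reversal in which the list was called as fallen, to 0.48 without 35 mM replicate 1. The mean of the acinar list at 20 against 11.8 mM came to 0.0090 with the acinar covariate, where the direction of its test turned, by construction. With the replicate number as a block the counts were 13, 74, 3 and 51 genes, 10 shared and 26 list calls. The main fit had no such block, because the labels do not state that replicate numbers pair samples. Same-numbered libraries had correlations of -0.146 to 0.0459, against -0.159 to 0.163 for different numbers, and 2 of 9 libraries were closest to their own number. These values show no sign of a pairing but cannot exclude one.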

Other observations

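The genes named in the next sentences and the tally of signs at 20 mM were chosen after their values were seen, whereas the test of the stromal and immune score was fixed before its result was seen. At 35 mM further genes rose or fell by edgeR's test. Odc1 and Srm, enzymes of polyamine synthesis, rose by 0.64 ± 0.16 (adjusted p = 0.0444) and 0.62 ± 0.15 (adjusted p = 0.0317) on the log2 scale, and Pycr1, an enzyme of proline synthesis, by 0.95 ± 0.16 (adjusted p = 8.44e-04). Sec11c, a subunit of the signal peptidase, stood at 1888 ± 351, 3107 ± 341 and 2816 ± 59.8 CPM at 11.8, 20 and 35 mM. It rose at both raised concentrations (0.72 and 0.58). Its call at 20 mM was lost with the acinar covariate (adjusted p = 0.147 by edgeR). Bace2, a protease of beta cells, rose by 0.66 ± 0.12 and the growth factor receptor gene Igf1r by 0.57 ± 0.14. Dusp6, a phosphatase of the ERK pathway, rose by 1.53 ± 0.31 at a low level, from 2.96 ± 0.215 to 8.62 ± 0.526 CPM. Idh2, a mitochondrial dehydrogenase, had a log2 fold change of -0.77 ± 0.18 and fell, as did Resp18, a granule protein, at -0.59 ± 0.14, with a count that is uncertain because its exons overlap a gene on the opposite strand.

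Of the 84 genes called at 35 mM, all 84 had the same sign at 20 mM and 76 had a smaller change there, a value that the shared 11.8 mM libraries and the choice of genes by their 35 mM value both raise.

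The fall of immediate early genes at 35 mM was set against a loss of stromal and immune cells, whose markers fell beside them. With the mean of both marker lists as a covariate over the 9 libraries the effect on the mean log2 CPM of the list was -0.5845 ± 0.153 (SE), against -0.53 ± 0.113 without it. This argues against that explanation as far as the score tracks those cells. Endothelial markers, not called at 35 mM (median -0.49, adjusted p = 0.117 by camera), were not part of the score. Differences in handling between the cultures were not tested, and glucose may account for the fall.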
